A study of Bos taurus with 6 samples.

How the data were processed

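RNA-seq was carried out on bovine trophoblast cells at 3 stages of culture, with 2 libraries per stage and 6 in all. Per the labels, undifferentiated trophoblast stem cells grew on mouse embryonic fibroblast feeders in LCDM, a medium for cells of extended potency. Differentiated cells grew on plates coated with collagen IV, in medium with forskolin, an activator of adenylyl cyclase that raises cyclic AMP, and an inhibitor of the kinase ROCK, and were taken at day 4 or day 10. Feeders, growth surface and medium therefore changed together with stage. Per the labels' protocols, RNA was extracted with the RNeasy Micro kit, libraries were made with the NEBNext Ultra II RNA kit and sequenced as pairs of 150 base reads, and base calls were converted with bcl2fastq 2.17. The series design text speaks of 3 replicates per time point, and 2 per stage are analysed here. Titles number the libraries of each stage 1 and 2, and per the labels' descriptions the library names begin with C1 for number 1 and B4 for number 2 at all 3 stages. The labels do not say what these prefixes mean, whether cell lines, animals, cultures or something else. Nothing else in the labels says that the libraries of a stage came from separate cultures or animals. By the labels alone the p-values then measure only the spread between these samples, which may be technical, although 9 genes had at least 50 counts in every library of 1 number and 0 in every library of the other.

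The authors deposited raw read counts per gene for 36075 genes and a second table that holds TPM values, counts corrected for gene length and scaled to a fixed total, beside the same counts for 18052 genes. Per the submitters' processing notes, fastp, STAR and featureCounts were used. Their versions, the genome build, the annotation and the strand setting are not given in the sources used here, so no coordinates are printed, and genes that overlap or lie antisense to each other may share reads. TPM recomputed from the counts and gene lengths matched the deposited TPM to within 4.73e-11. The TPM table held the genes with more than 50 counts over the 6 libraries: its lowest total was 51, and the highest total outside it was 50. It gave a symbol for 13605 genes and only an Ensembl identifier for 4447. In all, 51 symbols stood on more than 1 gene. All genes in the count table carried an identifier, and 0 lines named no gene. Genes of multicopy families, which include the prolactin-related proteins, the pregnancy-associated glycoproteins, the Kunitz domain proteins and the interferon tau genes, may share reads with near-identical copies, and their values are uncertain to that extent.

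Counts were tested with edgeR 4.0.16 in R 4.3.3, using its quasi-likelihood F test with default settings. All 6 libraries entered a single fit with a mean per stage, so that the stages shared an estimate of the spread. Genes were filtered with filterByExpr, which left 18618 genes, 5061 of them without a symbol. Libraries were scaled with TMM, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. The fit had 3 residual degrees of freedom, 2.64 prior degrees of freedom and a common biological coefficient of variation of 0.484. CPM values, counts scaled to a fixed library total, were computed from the deposited counts and TMM-scaled library sizes, and are given as mean ± SD with n = 2 per stage. Fold changes are on the log2 scale with standard errors from edgeR. DESeq2 1.42.0 was run with default settings as an alternative, and its adjusted p-values are named as such.

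Before the data were examined, 38 gene lists were fixed. They covered trophoblast identity (trophoblast stem cell regulators, pan-trophoblast markers, syncytialisation genes, steroidogenesis, imprinted genes, placental transporters, and the interferon tau, prolactin, pregnancy-associated glycoprotein and trophoblast Kunitz domain families). They covered signalling (prostaglandin, cyclic AMP, WNT, LIF and STAT3, TGF-beta and BMP, YAP and TEAD, interferon-stimulated genes, angiogenic factors) and growth (DNA replication, mitosis, CDK inhibitors and p53 targets, ribosomal proteins). They covered metabolism and stress (cholesterol, fatty acids, glycolysis and hypoxia, oxidative phosphorylation, unfolded protein response) and cell adhesion and shape (integrins with laminins and proteases, epithelial-mesenchymal transition, epithelial junctions, stratified epithelium), with MHC class I and antigen processing. Markers of other cell types were listed as well: fibroblast feeders, hypoblast and endoderm, pluripotent cells, amnion and primitive streak, endothelium and immune cells. Lists with at least 5 measured members, 35 in all, were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. The pattern used to collect MHC genes also took in BOLA1 and BOLA3, which are not MHC genes. Member counts are given over all genes tested and adjusted over the list alone. The adjustment over the list alone carries no correction over the lists or the comparisons. Summed over the lists, 15, 28 and 9 members passed it at day 4, at day 10 and between the times.

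The genes named in the text follow a rule written at the same time. It takes, per comparison, up to 6 genes in each direction with the largest fold change among called genes that have a symbol, no overlap between the libraries of the stages and a mean of at least 10 CPM. It adds 25 anchor genes whatever their result, 19 of which were measured (EOMES, IFNT2, PRP1, PAG2, PPARG and POU5F1 were not). From each list described it takes up to 4 called members, or the 2 with the highest mean where none was called, and from the feeder list the members with the highest mean. Because edgeR called no gene, the parts of the rule that need a call were also applied to the DESeq2 calls, a choice made after the data were seen. PAG17, PRP9, DKK1, MXI1, URAD, NAA11, CBLN4, PEG10, ACTA2 and, between day 4 and day 10, LIFR were chosen after their values were seen.

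Total counts ran from 63433424 to 78531310 per library, and 3 counts in the smallest library correspond to 0.0473 CPM, a floor that covers counting error only. The pipeline was tested on simulated counts for day 10 against undifferentiated, drawn for the 18618 genes from the real means and library sizes in 3 simulations with 200 changed genes each. edgeR recovered 0.667%, 27.3%, 63.3% and 85.3% of genes changed by 2, 4, 8 and 16 times, with 24 unchanged genes called in all. DESeq2 recovered 10%, 74%, 89.3% and 96%, with 306 unchanged genes called. Its recovered genes numbered 15, 111, 134 and 144 of 150 per fold. Unchanged genes thus made up far more of its calls than the threshold of 0.05 allows. DESeq2 adjusted p-values given below may therefore be too small. camera called 3 of 3 lists of 20 members raised by 2 times and 0 of 105 unchanged lists. Genes were drawn independently and the unchanged lists were taken at random, so these counts do not test list calls where genes are correlated. In the real lists at day 10 against undifferentiated, the estimated correlation ran from -0.122 for amnion and primitive streak markers to 0.864 for ribosomal proteins. For the comparisons that share the undifferentiated libraries, all 6 libraries were also simulated 20 times from a single mean and a single spread per gene. This leaves out any deviation that libraries of the same number share, and the wider spread of the undifferentiated pair. Libraries of 1 number were checked for shared deviations from their stage means, and 0 of 8 symbols meant to tell the sex of the cells were found in the tables. Alternatives were other scalings, other filters, only the stages compared, a robust or bias-adjusted spread, a minimum fold of 1.5, DESeq2, limma on log2(TPM + 1) and log2(TPM + 0.1), the replicate number as a block, and leaving out each library in turn. No deposited library was left out of the reported fit.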

Results

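Bovine trophoblast stem cells, which give rise to the outer epithelium of the placenta, were profiled by RNA-seq while undifferentiated and after 4 and 10 days of differentiation on collagen IV with forskolin and a ROCK inhibitor. Per its title, the series concerns directed differentiation of these cells as a culture model of the cattle placenta. Each stage had 2 libraries, numbered 1 and 2. Total counts were 63433424 and 78531310 for undifferentiated libraries 1 and 2, 75100340 and 71822753 at day 4 and 75680932 and 75642504 at day 10. Values are CPM as mean ± SD (n = 2) and log2 fold changes with their standard errors.

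Trophoblast genes differed widely in level. KRT8, a keratin of simple epithelia, stood at 4661 ± 1027 CPM in undifferentiated cells, 5206 ± 1116 at day 4 and 4767 ± 1272 at day 10. The trophoblast transcription factors GATA3 (261 ± 62.6 CPM undifferentiated, 357 ± 40.7 at day 10) and TFAP2C (161 ± 45.1 and 175 ± 3.44) were also expressed, and PTGS2, which makes prostaglandin precursors, stood at 6353 ± 382, 6361 ± 118 and 6449.5 ± 497 CPM at the 3 stages. The libraries of a stage were far apart for several regulators. CDX2, a determinant of trophectoderm fate, read 30.4 and 145 CPM in undifferentiated libraries 1 and 2, and ELF5, a stem cell regulator of trophoblast, 0.277 and 17.7. TP63, a transcription factor of epithelial progenitors, read 179 and 33.3. HAND1, linked to trophoblast giant cells, read 236 and 34.5.

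The libraries differed by number as well as by stage. The first principal component held 43.3% of the variance and separated number 1 from number 2 at every stage, and the second held 23.0% and ordered the stages. The gap between numbers on the first component was 197 for undifferentiated cells, 77.6 at day 4 and 83.2 at day 10. The median absolute log2 difference between the libraries of a stage was 0.64, 0.29 and 0.35 in the same order, so that the undifferentiated pair was the least alike. Protein-coding mitochondrial genes took 6.38% and 2.18% of counts in undifferentiated libraries 1 and 2, against 3.69% and 4.42% at day 4 and 6.50% and 5.37% at day 10. Ribosomal protein genes took 2.31% and 4.06% in undifferentiated libraries 1 and 2, and between 2.24% and 2.79% in the differentiated libraries.

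**Figure D1:**
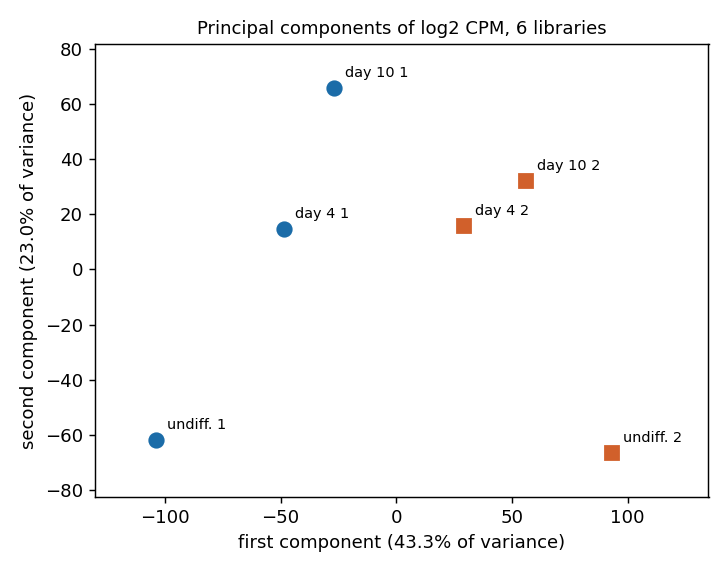
Each point is a library, placed by the first (43.3% of variance) and second (23.0%) principal components of log2 CPM; circles are libraries numbered 1 and squares those numbered 2. The numbers part along the first component at each stage, and the undifferentiated pair is the widest at 197 units.

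The first comparison asked what had changed after 4 days of differentiation. Genes of DNA replication were higher at day 4 in all 18 measured members, with a median log2 fold change of 0.56, and mitosis genes in all 20, with a median of 0.44. CCNE1, the cyclin that starts DNA replication, stood at 16.5 ± 0.159 CPM in undifferentiated cells and 36.7 ± 1.77 at day 4. Genes of glycolysis and the hypoxia response were lower in all 17 measured members, with a median of -1.10. ENO1, a glycolytic enzyme, stood at 2321 ± 489 and 1045 ± 128 CPM, and ADM, which encodes the vasodilator adrenomedullin, at 20.3 ± 17.2 and 1.75 ± 1.63. Type I collagen genes, which are among the fibroblast markers, were lower too, COL1A1 (ENSBTAG00000013103) at 72.9 ± 37.3 and 7.56 ± 4.44 CPM.

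No single gene passed edgeR's test at day 4. It called 0 of 18618 genes, with a smallest adjusted p of 0.519 (for MXI1 among others), 1434 genes at an unadjusted p under 0.05 and 930.9 expected there by chance. DESeq2 called 228, 83 higher and 145 lower, 45 of them without a symbol. In groups simulated without any change it called 65.8 on average, between 52 and 89. The simulations gave every stage the same spread per gene, although the undifferentiated pair was the least alike. They may therefore give too few chance calls. Deviations that libraries of the same number share were left out too, which may act the other way, since such deviations largely cancel between stage means. With a library left out, the DESeq2 count was 2251 without undifferentiated library 1, 1431 without undifferentiated library 2, 50 and 32 without day 4 libraries 1 and 2, and 142 and 143 without day 10 libraries 1 and 2, and edgeR called 1 gene without undifferentiated library 1.

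Among the genes that DESeq2 called at day 4 with a symbol, no overlap between the libraries of the stages and a mean of at least 10 CPM, the largest increases belonged to the smooth muscle actin gene ACTG2, the lysozyme gene LYZ3, PRXL2A, ARID5B, the KIT ligand gene KITLG and the zinc finger gene ZNF215. PRXL2A stood at 85.7 ± 36.8 CPM in undifferentiated cells and 545 ± 28.4 at day 4, a log2 fold change of 2.67 (SE 0.41) with a DESeq2 adjusted p of 3.24e-06 and an edgeR adjusted p of 0.519. KITLG stood at 4.66 ± 2.90 and 24.2 ± 4.58 CPM, with a fold change of 2.37 (SE 0.50) and a DESeq2 adjusted p of 0.00168. Within these limits the largest decreases were those of STC2, which encodes the secreted glycoprotein stanniocalcin 2, FOSB, COL1A2, TMEM35A, ADM and NRN1. STC2 stood at 22.7 ± 24.4 CPM and 1.32 ± 2.01e-04, a fold change of -4.10 (SE 0.98) with a DESeq2 adjusted p of 2.05e-04. CYP11A1, the enzyme that begins steroid synthesis by removing the side chain of cholesterol, stood at 113 ± 6.23 CPM in undifferentiated cells and 216 ± 7.74 at day 4, with a fold change of 0.93 (SE 0.18) and a DESeq2 adjusted p of 0.0234, and it alone of 12 steroidogenesis genes passed when adjusted over the list alone. MXI1, a MAX-binding repressor chosen after its values were seen, stood at 28.4 ± 2.00 and 8.08 ± 0.354 CPM (fold change -1.81, SE 0.20, DESeq2 adjusted p = 3.32e-08).

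camera called 8 of the 35 lists tested at day 4, 3 higher and 5 lower. DNA replication was called higher (camera adjusted p = 6.09e-10, and adjusted p = 0.332 with an estimated correlation), and 4 of its members, CCNE1 among them, passed when adjusted over the list alone. Mitosis genes were called higher (camera adjusted p = 1.37e-07, and adjusted p = 0.656 with an estimated correlation), with 0 members passing over the list alone. Glycolysis and the hypoxia response were called lower (camera adjusted p = 8.96e-10, and adjusted p = 0.332 with an estimated correlation), with 3 members, ENO1 among them, passing over the list alone, while DESeq2 called ADM and ENO1. By number, the median change of the DNA replication genes was 0.67 and 0.60 in numbers 1 and 2. That of the glycolysis and hypoxia genes was -0.87 and -1.22. These medians by number were not tested.

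Lists tied to mesenchyme and squamous epithelium were also called lower at day 4. The epithelial-mesenchymal transition list had a median of -2.48 with all 8 members lower (camera adjusted p = 4.38e-05, and adjusted p = 0.332 with an estimated correlation) and 0 passing over the list alone. DESeq2 called 2 of these, the intermediate filament gene VIM (175 ± 202 CPM undifferentiated, 22.4 ± 8.86 at day 4) and the transcription factor TWIST1 (4.77 ± 2.56 and 0.775 ± 0.356), both of which are also fibroblast markers. The fibroblast markers had a median of -0.93, with 14 of 19 lower (camera adjusted p = 0.0138, and adjusted p = 0.758 with an estimated correlation), 2 passing over the list alone (COL1A1 and COL1A2) and 4 called by DESeq2. Genes of stratified epithelium were lower in all 8 measured members, with a median of -1.60 (camera adjusted p = 0.00188, and adjusted p = 0.332 with an estimated correlation), and 1, the keratin KRT15, passed over the list alone (21.4 ± 6.43 and 4.85 ± 0.381 CPM, DESeq2 adjusted p = 9.92e-06). Ribosomal protein genes were lower in 63 of 65, with a median of -0.50 (camera adjusted p = 4.84e-09, and adjusted p = 0.840 with an estimated correlation), 0 passing over the list alone. RPSA stood at 2226 ± 1050.3 and 1387 ± 160.3 CPM. Per the labels, feeders were part of the undifferentiated cultures alone.

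Interferon-stimulated genes were called higher at day 4 with a median of 0.26 (camera adjusted p = 0.00651, and adjusted p = 0.840 with an estimated correlation), 0 passing over the list alone, but the numbers disagreed: the median change was -0.52 and 2.10 in numbers 1 and 2. Without undifferentiated library 2 the list was called lower, at -0.43 with a camera adjusted p of 0.0293, and without undifferentiated library 1 it stood at 1.99. Without undifferentiated library 1, 4 of the 8 calls were lost: mitosis (median 0.27, camera adjusted p = 0.0512), epithelial-mesenchymal transition (-1.51, 0.0593), stratified epithelium (-0.70, 0.0717) and fibroblast markers (-0.16, 0.786). Without undifferentiated library 2 the ribosomal call was lost (-0.090, 0.723), the medians of mitosis genes (0.73) and fibroblast markers (-1.72) were larger, and camera called 19 lists in place of 8. The fibroblast call was also lost without day 4 library 2 (median -0.86), day 10 library 1 (-0.92) or day 10 library 2 (-0.95). These medians stayed near the -0.93 with all libraries. Without day 4 library 1 the fibroblast median was -1.61. The ribosomal median was -0.83 without undifferentiated library 1.

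**Figure D2:**
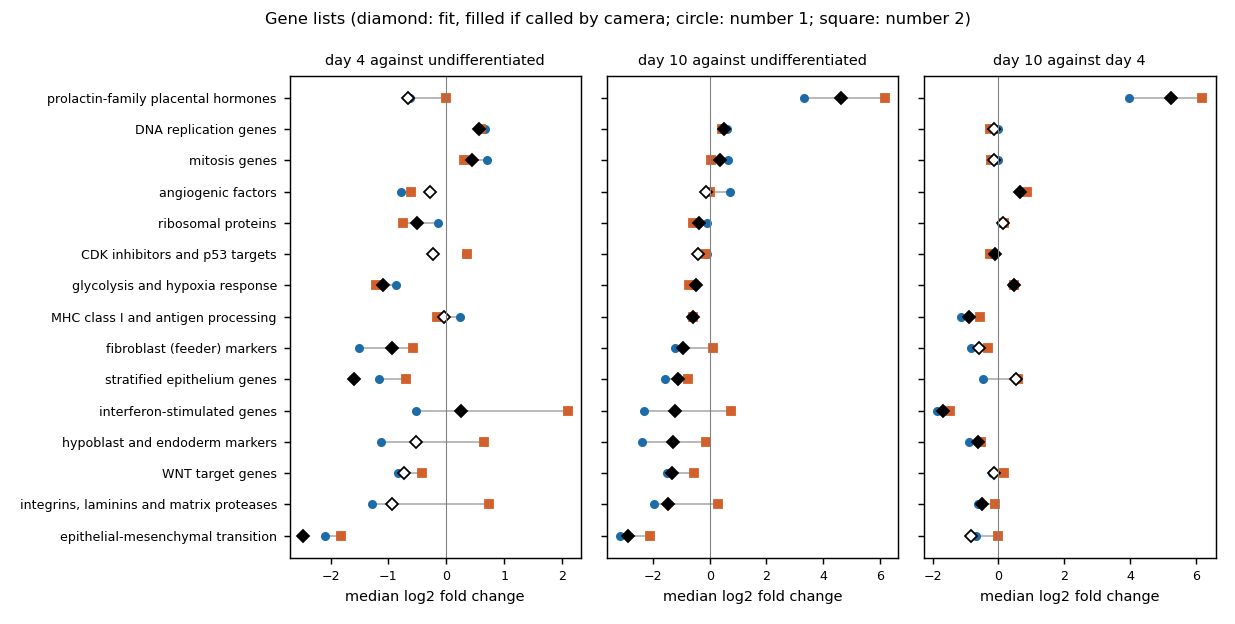
Median log2 fold change of each list called by camera in at least 1 comparison, in 3 panels for day 4 and day 10 against undifferentiated and day 10 against day 4; diamonds are fitted values, filled where camera called the list, circles and squares the medians of numbers 1 and 2. Interferon-stimulated genes moved apart by number at day 4 (-0.52 and 2.10) and together between day 4 and day 10 (-1.85 and -1.46).

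The second comparison set day 10 against undifferentiated cells. Several genes for placental hormones and secreted proteins had higher means at day 10. PRP14 (ENSBTAG00000062760), of the prolactin-related placental hormones, stood at 2.18 ± 3.09 CPM in undifferentiated cells and 78.9 ± 11.9 at day 10. CSH2, a placental lactogen gene, stood at 0.0326 ± 0.0461 and 2.42 ± 0.652. TKDP4 (ENSBTAG00000013950), a trophoblast Kunitz domain protein, stood at 604 ± 351 and 4019 ± 189.7 CPM. PGF (ENSBTAG00000013688), the placental growth factor gene, stood at 0.307 ± 0.211 and 14.2 ± 1.42, and FST (ENSBTAG00000003329), the activin-binding protein follistatin, at 1.86 ± 0.936 and 37.1 ± 9.59. Several fibroblast markers had lower means, COL1A2 at 36.9 ± 24.7 and 0.863 ± 0.184 CPM, while COL5A1, a collagen gene on the same list, stood at 249 ± 317 and 229 ± 133. SPARC, a matrix glycoprotein that is not on that list, stood at 53.2 ± 34.5 and 1.69 ± 0.238 CPM.

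edgeR called 0 of 18618 genes at day 10, with a smallest adjusted p of 0.366 (for URAD among others) and 1428 genes at an unadjusted p under 0.05, where chance gives 930.9. DESeq2 called 393, 174 higher and 219 lower, 67 of them without a symbol, against 68.3 on average (41 to 100) in simulated unchanged groups. These simulations also left out the wider spread of the undifferentiated pair and may for that reason give too few chance calls. They left out as well the deviations that libraries of the same number share, which may act the other way. Without undifferentiated library 2 edgeR called 150 genes, 36 higher and 114 lower, and without undifferentiated library 1 it called 2. The DESeq2 count was 1872 and 1826 without undifferentiated libraries 1 and 2, 204 and 227 without day 4 libraries 1 and 2, and 52 and 154 without day 10 libraries 1 and 2.

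The prolactin family was called higher at day 10, with a median log2 fold change of 4.62 over 5 measured members, 3 of them higher (camera adjusted p = 0.0117, and adjusted p = 0.537 with an estimated correlation), and 0 passed over the list alone. CSH2 had a fold change of 6.22 (SE 1.68) with a DESeq2 adjusted p of 4.70e-04, and PRP14 of 5.18 (SE 2.62) with a DESeq2 adjusted p of 0.848. PRP14 had 4.37 and 0 CPM in undifferentiated libraries 1 and 2 and 70.5 and 87.3 at day 10. PRP3 stood at 0.106 ± 0.150 and 2.57 ± 0.245 CPM. The call was lost without undifferentiated library 2 (median 3.59) or day 10 library 2 (4.51), against a median of 4.62 with all libraries. Without undifferentiated library 1 the median was 10.52, a value set against a library at 0 for 4 of these genes that depends on the prior count. The pregnancy-associated glycoproteins, with 3 measured members, were too few to test as a list. Of these, 2 passed over the list alone at day 10: PAG7 at 0.368 ± 0.333 and 6.39 ± 0.738 CPM (fold change 4.13, SE 1.29, DESeq2 adjusted p = 0.00408) and PAG17, chosen after its values were seen, at 0.0489 ± 0.0691 and 5.33 ± 0.00923 CPM (fold change 6.79, SE 1.64, DESeq2 adjusted p = 0.143). PAG1, whose symbol other species also use for an unrelated adaptor protein, stood at 11.3 ± 11.1 and 14.2 ± 10.9 CPM. Of the 2 Kunitz domain genes measured, TKDP4 passed over the list alone (fold change 2.73, SE 0.58, DESeq2 adjusted p = 3.40e-04), and TKDP2 stood at 0.438 ± 0.302 and 0.752 ± 0.452 CPM. For interferon tau, the ruminant signal of early pregnancy, IFNT read 4.73 and 4.54 CPM in undifferentiated libraries 1 and 2 and 4.83 and 25.6 at day 10, and IFNT3 3.94 and 4.41 and 3.63 and 24.3, with 0 of the 2 passing over the list alone. Reads of these families may be shared between near-identical copies, so that values of single members are uncertain.

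**Figure D3:**
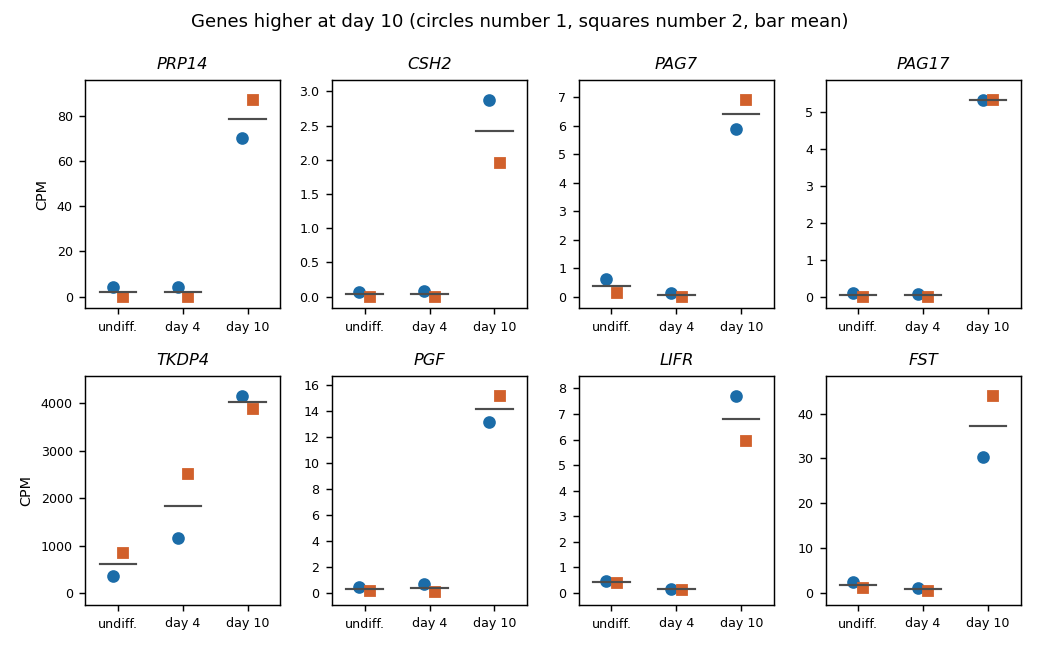
CPM of 8 genes in each library by stage; circles are number 1, squares number 2 and bars the stage mean. Each of the 8 was higher in both day 10 libraries than in either undifferentiated library, with TKDP4 at 4153 and 3885 CPM at day 10 and 356 and 853 before differentiation.

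Among DESeq2 calls at day 10 within the same limits, a mean of at least 10 CPM included, the largest increases were those of PGF, GPX6, GPLD1, FST, ATP2A3 and FRAS1. PGF had a fold change of 5.53 (SE 1.21) with a DESeq2 adjusted p of 2.72e-06 and an edgeR adjusted p of 0.509, and FST of 4.32 (SE 0.61) with 8.87e-11 and 0.442. GPX6, a glutathione peroxidase, stood at 0.460 ± 0.295 and 20.9 ± 9.71 CPM, and FRAS1, a basement membrane protein, at 0.586 ± 0.367 and 10.6 ± 2.65. The largest decreases within these limits were those of the chemokine gene CCL2 (103 ± 136 and 1.43 ± 0.608 CPM), the cadherin gene CDH11 (19.7 ± 14.1 and 0.367 ± 0.371), a signal recognition particle RNA named Metazoa_SRP, PRRX1, COL1A2 and SPARC. COL1A2 had a fold change of -5.41 (SE 0.62) with a DESeq2 adjusted p of 1.35e-17 and an edgeR adjusted p of 0.366. PRRX1 and COL1A2 are on the list of fibroblast markers, and per the labels feeders were part of the undifferentiated cultures alone. Feeder RNA and a change of the trophoblast cells were not told apart in these decreases. URAD, a gene of uric acid breakdown chosen after its values were seen, stood at 5.46 ± 1.08 CPM undifferentiated, 17.2 ± 1.80 at day 4 and 30.4 ± 3.35 at day 10. LIFR (ENSBTAG00000010423), the receptor for leukaemia inhibitory factor, stood at 0.426 ± 0.0424 and 6.82 ± 1.25 CPM (fold change 4.00, SE 0.42, DESeq2 adjusted p = 2.24e-14).

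camera called 13 lists at day 10, 3 higher and 10 lower. DNA replication was higher in 17 of 18 members, with a median of 0.50 (camera adjusted p = 2.92e-06, and adjusted p = 0.486 with an estimated correlation; 0 over the list alone). Mitosis genes were higher in all 20, with a median of 0.36 (camera adjusted p = 4.69e-04, and adjusted p = 0.756 with an estimated correlation; 0 over the list alone). The epithelial-mesenchymal transition list was lower in all 8 members, with a median of -2.88 (camera adjusted p = 1.90e-06, and adjusted p = 0.486 with an estimated correlation). Of these members 5 passed over the list alone, and DESeq2 called CDH2, ZEB2, VIM and TWIST1, with ZEB2 at 9.33 ± 8.90 and 0.334 ± 0.398 CPM. Fibroblast markers had a median of -0.93, 13 of 19 lower (camera adjusted p = 9.61e-04, and adjusted p = 0.537 with an estimated correlation), with 4 passing over the list alone and 6 called by DESeq2, and in number 2 alone 10 of the 19 were higher. COL1A1 stood at 72.9 ± 37.3 and 4.42 ± 1.18 CPM and VIM at 175 ± 202 and 13.6 ± 4.71. These markers stood at 1 CPM or more in both libraries for 11 of 19 members in undifferentiated cells and 7 of 19 at day 10, so that trophoblast cultures without feeders also held several of them.

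WNT target genes had a median of -1.35, with 8 of 12 lower (camera adjusted p = 0.0181, and adjusted p = 0.486 with an estimated correlation), and 7 passed over the list alone, 5 lower and 2 higher. DESeq2 called 4 lower, TCF7, TNFRSF19 (8.71 ± 3.06 and 2.42 ± 0.662 CPM), AXIN2 (11.4 ± 1.72 and 4.05 ± 1.64) and LEF1. DKK1, a secreted WNT inhibitor on the same list and chosen after its values were seen, was among the 2 higher, with 0.0326 ± 0.0461 and 9.71 ± 2.03 CPM (edgeR adjusted p = 0.554). Integrins, laminins and matrix proteases had a median of -1.48, 17 of 22 lower (camera adjusted p = 0.00717, and adjusted p = 0.824 with an estimated correlation; 0 over the list alone), with SPP1, the integrin ligand osteopontin, at 202 ± 254 and 19.1 ± 1.42 CPM. Hypoblast and endoderm markers were lower in all 9 members, with a median of -1.29 (camera adjusted p = 0.00231, and adjusted p = 0.537 with an estimated correlation; 0 over the list alone), and APOA1 stood at 8.88 ± 3.02 and 1.30 ± 0.951 CPM. Genes of stratified epithelium were lower in all 8, with a median of -1.12 (camera adjusted p = 0.00307, and adjusted p = 0.486 with an estimated correlation), 1 of them, the desmosomal cadherin DSG3, passing over the list alone at 822 ± 5.31 and 367 ± 47.1 CPM. Glycolysis and the hypoxia response were lower in 15 of 17, with a median of -0.47 (camera adjusted p = 0.00474, and adjusted p = 0.537 with an estimated correlation; 0 over the list alone). Interferon-stimulated genes were lower in 16 of 17, with a median of -1.24 (camera adjusted p = 8.68e-04, and adjusted p = 0.767 with an estimated correlation; 0 over the list alone). The list of MHC class I and antigen processing was lower in 6 of 7, with a median of -0.58 (camera adjusted p = 0.0161, and adjusted p = 0.486 with an estimated correlation; 0 over the list alone). Ribosomal proteins were lower in 63 of 65, with a median of -0.37 (camera adjusted p = 6.16e-05, and adjusted p = 0.890 with an estimated correlation; 0 over the list alone).

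Several of these calls did not hold with a library left out. Without undifferentiated library 1, 8 of the 13 were lost, with camera adjusted p from 0.0553 to 0.344. The medians of interferon-stimulated genes (0.59) and of integrins, laminins and matrix proteases (0.38) then turned positive, and those of mitosis genes (0.053), fibroblast markers (-0.11), hypoblast markers (-0.51), WNT targets (-0.73) and epithelial-mesenchymal transition (-1.77, still called) came nearer to 0. The other calls lost there were stratified epithelium (camera adjusted p = 0.107) and MHC class I (0.0553), while ribosomal proteins (-0.69) and glycolysis (-0.91) moved further down. Without undifferentiated library 2, 4 calls were lost (camera adjusted p from 0.115 to 0.236): MHC class I, glycolysis (median -0.20), the prolactin family and ribosomal proteins, whose median became 0.068. The medians of interferon-stimulated genes (-2.02), integrins (-2.25), mitosis genes (0.59) and WNT targets (-0.77) also moved by more than 1.5 times without it. The WNT call was lost without day 4 library 1 (median -1.37), day 4 library 2 (-1.35) or day 10 library 1 (-0.84). Its median with all libraries was -1.35. The calls of MHC class I (-0.59) and glycolysis (-0.53) were lost without day 10 library 1, where the ribosomal median was -0.24. Glycolysis stood at -0.96 without day 10 library 2. By number, the median change of interferon-stimulated genes was -2.34 and 0.75 in numbers 1 and 2, that of integrins -1.96 and 0.29, that of fibroblast markers -1.22 and 0.10, that of mitosis genes 0.64 and 0.060 and that of hypoblast markers -2.39 and -0.13, whereas the epithelial-mesenchymal transition list had -3.17 and -2.10 and DNA replication 0.62 and 0.43.

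The third comparison, day 10 against day 4, set 2 stages that were both grown without feeders. Camera called the prolactin family higher at day 10 than at day 4 and interferon-stimulated genes lower, though neither with an estimated correlation (adjusted p = 0.443 and adjusted p = 0.539 with an estimated correlation), and 0 members of either passed when adjusted over the list alone. All 5 prolactin-family genes were higher, with a median log2 fold change of 5.23, and PRP14, which neither edgeR nor DESeq2 called, stood at 2.09 ± 2.96 CPM at day 4 and 78.9 ± 11.9 at day 10. All 17 interferon-stimulated genes were lower, with a median of -1.68. RSAD2, an antiviral enzyme, stood at 25.8 ± 13.7 and 0.962 ± 0.211 CPM.

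edgeR called 0 of 18618 genes between day 4 and day 10, with a smallest adjusted p of 0.529 (LIFR) and 555 genes at an unadjusted p under 0.05, below the 930.9 that chance gives. DESeq2 called 41, 29 higher and 12 lower, 13 of them without a symbol, and in simulated unchanged groups 63.9 on average (43 to 80). The fit and these simulations leave out the deviations that libraries of the same number share between stages, so the 2 counts do not show that the stages differ less than unchanged groups would. Its count was 316 and 334 without undifferentiated libraries 1 and 2, 18 and 23 without day 4 libraries 1 and 2, and 11 and 26 without day 10 libraries 1 and 2. Within the limits on symbol, overlap and a mean of at least 10 CPM, the DESeq2 calls with the largest increases were FST, PGF, ATP2A3, FOSB, ADM and FAM151A. FST stood at 0.799 ± 0.468 and 37.1 ± 9.59 CPM, a fold change of 5.53 (SE 0.65) with a DESeq2 adjusted p of 9.40e-18, and PGF had a fold change of 5.23 (SE 1.19) with a DESeq2 adjusted p of 4.64e-05. ATP2A3, a calcium pump of the endoplasmic reticulum, stood at 0.336 ± 0.397 and 12.1 ± 2.42 CPM. LIFR stood at 0.145 ± 0.0304 and 6.82 ± 1.25 CPM (fold change 5.53, SE 0.45, DESeq2 adjusted p = 3.54e-22). The decreases that met the rule were RSAD2 (fold change -4.74, SE 1.03, DESeq2 adjusted p = 2.38e-05), SPARC (11.7 ± 1.78 and 1.69 ± 0.238 CPM, DESeq2 adjusted p = 2.32e-04) and the zinc finger gene ZNF81 (14.0 ± 5.45 and 4.17 ± 0.788 CPM, DESeq2 adjusted p = 0.0179).

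camera called 8 lists between day 4 and day 10, 3 higher and 5 lower. The prolactin family was called higher (camera adjusted p = 1.78e-05, and adjusted p = 0.443 with an estimated correlation; 0 over the list alone), and CSH2 had a fold change of 5.89 (SE 1.62) with a DESeq2 adjusted p of 0.00196. Glycolysis and the hypoxia response were higher in 15 of 17 members, with a median of 0.48 (camera adjusted p = 1.18e-04, and adjusted p = 0.539 with an estimated correlation; 0 over the list alone). Angiogenic factors were higher in 6 of 8, with a median of 0.65 (camera adjusted p = 0.00377, and adjusted p = 0.443 with an estimated correlation), and 2, PGF and ADM, passed over the list alone. ADM stood at 1.75 ± 1.63 and 23.8 ± 1.76 CPM and belongs to both of these lists, as does VEGFA. Interferon-stimulated genes were called lower (camera adjusted p = 1.61e-15, and adjusted p = 0.539 with an estimated correlation; 0 over the list alone), with -1.85 and -1.46 in numbers 1 and 2, and DESeq2 called RSAD2 and IFIT2 among them. MX1, another antiviral effector, stood at 155 ± 13.0 and 63.4 ± 4.48 CPM. The list of MHC class I and antigen processing was lower in 6 of 7, with a median of -0.90 (camera adjusted p = 3.13e-04, and adjusted p = 0.443 with an estimated correlation; 0 over the list alone), with B2M, the light chain of MHC class I, at 195 ± 44.7 and 92.7 ± 14.4 CPM. Hypoblast and endoderm markers were lower in 8 of 9, with a median of -0.63 (camera adjusted p = 0.00280, and adjusted p = 0.591 with an estimated correlation; 0 over the list alone). CDK inhibitors and p53 targets were lower in 8 of 13, with a median of -0.091 (camera adjusted p = 0.00471, and adjusted p = 0.443 with an estimated correlation; 2 over the list alone), with the p53 regulator MDM2 at 233 ± 17.5 and 101 ± 5.41 CPM. Integrins, laminins and matrix proteases were lower in 17 of 22, with a median of -0.49 (camera adjusted p = 0.0309, and adjusted p = 0.904 with an estimated correlation; 0 over the list alone). Calls were lost without day 10 library 1 for hypoblast markers (camera adjusted p = 0.0974) and integrins (0.0758). They were lost without day 10 library 2 for CDK inhibitors (0.147), angiogenic factors (0.0689) and integrins (0.126), and without day 4 library 1 for CDK inhibitors (0.0642) and integrins (0.723, with a median of 0.11). Camera called 5 lists in place of 8 without day 10 library 2. Medians that moved by more than 1.5 times were those of CDK inhibitors (-0.16, -0.29 and -0.39 without day 4 library 1, day 4 library 2 and day 10 library 1), hypoblast markers (-0.95 without day 4 library 1 and -1.05 without day 10 library 2), MHC class I (-0.59 without day 10 library 1), integrins (-0.81 without day 10 library 1) and the prolactin family (10.45 without day 4 library 1, against a library at 0).

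**Figure D4:**
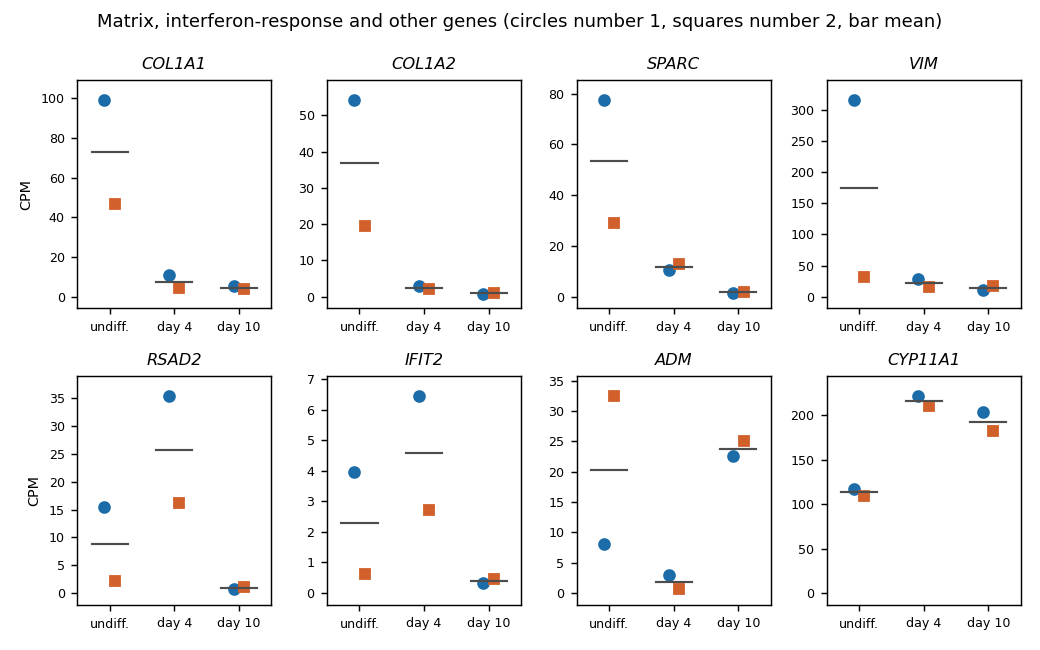
CPM of 8 genes in each library by stage; circles are number 1, squares number 2 and bars the stage mean. COL1A1, COL1A2, SPARC and VIM are highest before differentiation, RSAD2 and IFIT2 have their highest mean at day 4, ADM is lowest at day 4 with 2.90 and 0.592 CPM, and CYP11A1 is lowest before differentiation with 118 and 109 CPM.

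The changes at day 4 and at day 10 were compared with each other. DESeq2 called 118 genes in the same direction at both times, 53 higher and 65 lower, and 0 in opposite directions. Simulated unchanged groups shared 15.5 on average (8 to 34), and independent lists of these sizes among the 16891 genes tested in both would share 0.855 higher and 1.88 lower. The log2 fold changes at the 2 times correlated at 0.603 across genes, which are not independent replicates, against 0.502 (0.479 to 0.535) in the simulations, and their covariance was 0.600 against 0.372, a difference of 0.227. Both comparisons used the same 2 undifferentiated libraries, which were too few to split. The simulated comparisons shared their controls as well. They left out the wider spread of the undifferentiated pair, from which part of the excess may come. They also left out the deviations that libraries of the same number share. Each stage held a library of both numbers, so such deviations largely cancel between stage means and are not a likely source of the excess. The overlap of day 4 and day 10 calls by DESeq2 was 1334 and 1017 without undifferentiated libraries 1 and 2, 33 and 18 without day 4 libraries 1 and 2, and 29 and 56 without day 10 libraries 1 and 2. edgeR, which called 0 genes at either time, shared 0, and 1 without undifferentiated library 1.

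Markers of trophoblast state showed no call as groups. At day 10 against undifferentiated, the median log2 fold change was -0.17 for trophoblast stem cell regulators (camera adjusted p = 0.939), 0.078 for pan-trophoblast markers (0.982), 0.0089 for syncytialisation genes (0.764), 0.15 for steroidogenesis (0.238), -0.36 for placental transporters (0.413) and -0.20 for imprinted genes (0.866). All but that of placental transporters changed sign with a library left out. Without undifferentiated library 2 they were 0.28 for stem cell regulators, -0.10 for syncytialisation genes and 0.56 for imprinted genes. Without undifferentiated library 1 that of pan-trophoblast markers was -0.15. Without day 10 library 2 they were -0.11 for pan-trophoblast markers, -0.13 for syncytialisation genes and -0.0049 for steroidogenesis. Stem cell regulators stood at 0.056 without day 10 library 1 and syncytialisation genes at -0.0029 without day 4 library 1. Without undifferentiated library 1 placental transporters were called lower (median -0.31, camera adjusted p = 0.0124). For stem cell regulators and imprinted genes the camera test pointed upward although median and mean were negative, and for pan-trophoblast markers the mean was -0.011 beside a positive median. DESeq2 called 1 stem cell regulator and 1 syncytialisation gene, both lower and not named here. It called 1 steroidogenesis gene and 1 imprinted gene, both higher, and 0 pan-trophoblast markers and 0 placental transporters. GCM1, a transcription factor of trophoblast fusion, stood at 0.204 ± 0.288 CPM undifferentiated and 2.30 ± 0.00525 at day 10 (edgeR adjusted p = 0.707, DESeq2 0.256). PEG3, an imprinted zinc finger gene, stood at 589 ± 90.6 CPM and 1407 ± 435 (DESeq2 adjusted p = 0.0488), and HSD17B1, which activates oestrogen, at 0.472 ± 0.529 and 3.76 ± 2.11 (DESeq2 adjusted p = 0.0487). GATA2 stood at 492 ± 129.9 and 320.2 ± 94.5 CPM, CYP19A1, the aromatase gene, at 5.95 ± 7.50 and 12.9 ± 7.49, and HSD3B1 at 57.4 ± 12.1 and 58.6 ± 9.34. The proliferation marker MKI67 stood at 317 ± 59.4 and 360.4 ± 3.91 CPM, CCNB1 at 80.9 ± 24.0 and 101 ± 3.14, OVOL1 at 17.2 ± 4.54 and 20.1 ± 0.196 and CDKN1C at 69.7 ± 76.9 and 99.4 ± 18.8. edgeR called none of the genes in this paragraph, where 1428 genes had an unadjusted p under 0.05, and DESeq2 called those given here with an adjusted p under the threshold of 0.05.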

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

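The lists below are those that camera called between day 4 and day 10. Not all were called against undifferentiated cells. Angiogenic factors (camera adjusted p = 0.174 at day 4 and 0.668 at day 10) and CDK inhibitors and p53 targets (0.612 and 0.205) were called at neither time. The values give the difference between the fitted changes at day 10 and at day 4. The undifferentiated libraries cancel in that difference, which camera tested as day 10 against day 4. The fold changes therefore come from 4 libraries grown, per the labels, without feeders. The tests still took their spread from all 6 libraries, and whether feeder RNA remained at day 4 was not tested. The tests that weigh explanations in this part were chosen after the results were seen.

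Interferon-stimulated genes differed by -1.68 on the log2 scale (median of 17 genes), lower in both numbers. The prolactin-family placental hormones differed by 5.23, glycolysis and the hypoxia response by 0.48 and angiogenic factors by 0.65. MHC class I and antigen processing differed by -0.90, hypoblast and endoderm markers by -0.63, integrins, laminins and matrix proteases by -0.49, and CDK inhibitors and p53 targets by -0.091. With an estimated correlation in place of the preset of 0.01, camera called 0 of these 8, with adjusted p from 0.443 to 0.904.

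Placental hormone and glycoprotein genes (PRP14, PRP3, CSH2, PAG7 and PAG17) had higher means at day 10 than before differentiation. The choice among the 4 scalings tried cannot account for this, because the smallest of the 5 log2 fold changes was 4.10 over them. These scalings moved the median of all genes far less than that. The outcome was thus settled beforehand and does not test other errors of scaling. For PRP14, reads moved from other measured members of the prolactin family are argued against. The lowest day 10 sum of the family was 13.4 times the highest undifferentiated sum. PRP14 dominated that sum, with 70.5 of 76.3 and 87.3 of 92.4 CPM in day 10 libraries 1 and 2. The sum therefore cannot show whether reads of PRP14 were counted to PRP3 or CSH2, with day 10 means of 2.57 and 2.42 CPM. For the glycoproteins the same ratio was 0.918, because PAG1 dominated the sum and read 3.39 and 19.1 CPM in the undifferentiated libraries, so a shift of reads between PAG genes stays open. At day 4, with medium and surface already changed and no feeders, PRP14, PRP3, CSH2, PAG7 and PAG17 had means of 2.09, 0.0642, 0.0385, 0.0642 and 0.0385 CPM, so time in culture remains as an untested candidate explanation, and a delayed effect of medium or surface stays open.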

How the results depend on the processing

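Alternatives marked below as added, and every DESeq2 fit with a library left out or with a block, were chosen after the data were seen. Genes changed under edgeR stayed at 0 in all 3 comparisons under the other scalings, filters and spreads, limma on TPM, a minimum fold and the bias-adjusted fit (added). DESeq2 gave 228, 393 and 41 at day 4, at day 10 and between them, with an overlap of 118. With a library left out, edgeR gave 0 to 1 at day 4, 0 to 150 at day 10 and 0 between them, with an overlap of 0 to 1. The same ranges for DESeq2 (added) were 32 to 2251, 52 to 1872 and 11 to 334, with an overlap of day 4 and day 10 calls by DESeq2 of 18 to 1334. Of the 228 genes at day 4, 190 were among the 2251 called without undifferentiated library 1, and 27 among the 32 called without day 4 library 2. Leaving out a library leaves a stage with a lone sample that is assumed to vary like the others, and leaving out an undifferentiated library also removes the pair that differed most from the estimate of the spread.

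Gene lists called were 0 in each comparison with an estimated correlation and 0 with directional fry. Mixed fry called 2, 3 and 2. With a library left out they ranged from 7 to 19 at day 4 (19 without undifferentiated library 2), 10 to 13 at day 10 and 5 to 11 between them (5 without day 10 library 2), against 8, 13 and 8. Of the lists called with all libraries, the median changed sign with a library left out for 5. At day 4 this was that of interferon-stimulated genes (-0.43 without undifferentiated library 2 to 1.99 without undifferentiated library 1). At day 10 it was those of interferon-stimulated genes (-2.02 without undifferentiated library 2 to 0.59 without library 1), of integrins, laminins and matrix proteases (-2.25 to 0.38) and of ribosomal proteins (-0.69 without undifferentiated library 1 to 0.068 without library 2). Between day 4 and day 10 it was that of integrins, laminins and matrix proteases (-0.49 with all libraries, 0.11 without day 4 library 1). Among results of lists not called with all libraries, 55 medians changed sign, and 8 of these were then called, among them integrins at day 4 (1.16 without undifferentiated library 1). The cause was not tested. Scalings moved the median of all genes by less than 0.1. For single lists, 1309 alternatives kept the result, 89 lost a call, 51 gained a call, 110 moved and 4 reversed. For single named genes, 5920 kept it, 101 gained a call and 385 moved.

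Deviations of same-numbered libraries from their stage means correlated at 0.425, 0.441 and 0.434 for the 3 pairs of stages, and library names begin with C1 for number 1 and B4 for number 2 at every stage, which hints at a shared origin. The labels do not say what the prefixes mean, and each comparison has only 2 pairs, so the numbers were not treated as pairs in the reported fit. With the replicate number as a block, edgeR called 0 genes in each comparison with an overlap of 0, DESeq2 (added) called 454, 664 and 112 with an overlap of 249, and camera called 9, 13 and 11 lists. Depth limits genes under 0.0473 CPM in the smallest library. For the rest, 2 libraries per stage and the wide spread of the undifferentiated pair are both limits, which were not told apart.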

Other observations

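The tests of explanations in this part were chosen after the results were seen. Some lists that were called in no comparison held members that passed when adjusted over the list alone or that DESeq2 called, although edgeR called 0 of all genes at day 10, with 1428 of 18618 at an unadjusted p under 0.05 and 393 called by DESeq2. LIF and STAT3 response genes had a median of -0.085 (0.826) at day 10 against undifferentiated, where the value in brackets, here and below, is the camera adjusted p, yet 2 of its 9 members passed over the list alone, and fry's mixed test, which asks whether members change in either direction, gave an adjusted p of 0.0221. These were LIFR, higher, and STAT3 (2.49 ± 2.34 and 0.0197 ± 0.0278 CPM), lower; the STAT3 values are uncertain, since most cells express this gene. Among cyclic AMP response genes, with a median of -0.34 (0.826), the phosphodiesterase gene PDE4B stood at 1.11 ± 0.556 CPM undifferentiated and 9.02 ± 4.77 at day 10 (DESeq2 adjusted p = 5.12e-05), while EGR1 stood at 108 ± 108 and 85.3 ± 18.2. Endothelial markers, with a median of -0.78 (0.764), held PECAM1 at 0.802 ± 0.686 and 4.64 ± 1.22 CPM (DESeq2 adjusted p = 0.0208) and ESAM at 5.92 ± 4.03 and 1.28 ± 0.581 (DESeq2 adjusted p = 0.0343), which went opposite ways. Among immune cell markers, with a median of -0.96 (0.826), CSF1R stood at 0.123 ± 0.0127 and 1.06 ± 0.479 CPM (DESeq2 adjusted p = 0.0265).

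The other lists called in no comparison had these medians at day 10: TGF-beta and BMP response -0.48 (0.464), YAP and TEAD targets 0.067 (0.512), prostaglandin synthesis 0.022 (0.262), pluripotency genes -0.44 (0.764), amnion and primitive streak markers -0.090 (0.751), cholesterol biosynthesis -0.21 (0.173), fatty acid metabolism 0.20 (0.173), oxidative phosphorylation -0.11 (0.764), unfolded protein response 0.18 (0.826) and epithelial junctions -0.046 (0.842). At day 10, median, mean and camera direction did not share a sign for 9 of the 20 uncalled lists, among them LIF and STAT3, cyclic AMP, YAP and TEAD, amnion, unfolded protein response and junctions. Without undifferentiated library 1 camera called YAP and TEAD targets higher (median 1.48, adjusted p = 9.33e-07) and pluripotency genes lower (-1.01, 0.00723), and without undifferentiated library 2 it called the former lower (-0.58, 0.00491) and the latter higher (0.88, 0.0422). Calls were also gained for cyclic AMP (0.94, 0.0323, opposite in sign to the median with all libraries), cholesterol (-0.41, 0.0141) and oxidative phosphorylation (-0.38, 0.00723) without library 1, and for fatty acids (0.28, 0.0422) and, lower, TGF-beta (adjusted p = 0.00330) without library 2. Without a call, the sign also turned without library 1 for TGF-beta (0.48), amnion (0.094), immune cell markers (0.84) and junctions (0.13), and without library 2 for amnion (0.78) and oxidative phosphorylation (0.24). Without day 10 library 1 it turned for YAP and TEAD (-0.073), amnion (0.018) and junctions (0.034), and without day 10 library 2 for prostaglandin (-0.058) and junctions (0.0062). The medians that turned give no direction. With all libraries, the lowest camera adjusted p of these 20 lists was 0.174 at day 4, 0.173 at day 10 and 0.113 between the times.

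The median of the fibroblast marker genes was lower after the undifferentiated stage, at which feeders had been present, but at day 10 this rested on number 1 (median changes of -1.22 and 0.10 in numbers 1 and 2, with 10 of 19 markers higher in number 2). The choice among the 4 scalings cannot account for the lower median, since the highest value over them was -0.87 at day 10. These scalings moved the median of all genes far less than that. The outcome was thus settled beforehand and does not test other errors of scaling. RNA from the feeders in the undifferentiated libraries stays open as a possible explanation: the list lay at -0.59 between day 4 and day 10, both without feeders, where camera did not call it (adjusted p = 0.113, though 0.0494 without undifferentiated library 2 and 0.0168 without day 4 library 2), and feeders, surface, medium and stage changed together. Its 6 members with the highest means over all libraries differed between undifferentiated libraries 1 and 2 by unequal ratios. These were 19.2 for COL5A1, 36.1 for TAGLN, 9.95 for VIM, 0.732 for ACTA2, 2.13 for COL1A1 and 2.79 for COL1A2. That ranking took in genes that cultures without feeders also expressed, with COL5A1 at 229 ± 133 CPM at day 10. The unequal ratios therefore do not decide on feeder RNA. SPARC, which is not on the list, had a ratio of 2.69. Of the 11 markers at 1 CPM or more in both undifferentiated libraries, 6 were lower in both day 10 libraries than in either undifferentiated library. A change of the trophoblast cells themselves was not tested apart from feeder RNA.

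Libraries numbered 1 and 2 stood apart at every stage. A difference in depth is argued against at day 10, where the totals differed by 0.0508% while the libraries lay 83.2 apart on the first component. It was not tested for the undifferentiated pair, which had totals of 63433424 and 78531310 and lay 197 apart. Numbers swapped at a stage are argued against too: 9 genes had at least 50 counts in every library of 1 number and 0 in every library of the other, and regroupings that break the numbers gave 0 such genes. NAA11 read 0 and 61.1 CPM, 0 and 44.5 and 0 and 33.3 in libraries 1 and 2 of the 3 stages, and PEG10 and CBLN4 were likewise at 0 in number 1 alone. Cells of different origin behind the numbers may explain this, as a hypothesis that fits the lowest correlation of same-numbered deviations, 0.425, and that goes with the prefixes C1 and B4 of the library names, which follow the numbers at every stage and whose meaning the labels do not give.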
